A study of Mus musculus with 6 samples.

How the data were processed

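RNA of gastrocnemius muscle from 6 mice was measured, 3 libraries labelled WT and 3 labelled TRa_mKO, all given batch 1 by the labels. Per the labels' protocols, polyadenylated RNA was selected, libraries were stranded by dUTP incorporation and were prepared with a kit for the BGISEQ-500 instrument or an equivalent, and sequencing was paired-end. The submitters' processing notes name FastQC 0.11.9, MultiQC 1.12, Trimmomatic 0.39 and featureCounts, and the builds mm10, GRCm38.p6 and GRCm39, with no role or order. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. The authors deposited one table of estimated counts per gene, headed as read counts per the file headers, with no normalization. Between 9.6% and 10.0% of the values of a library were not whole, and which tool gave fractional counts is not stated. The values were rounded to whole numbers before any test. A gene with a fractional count in any library is said to share reads with other features, and its values are uncertain to that extent.

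The table listed 74693 features, of which 17034 had values in all libraries and 57659 had none. Mitochondrially encoded genes had 0 values, so their list, and the fit that leaves them out, were not run. The number of value columns given to no sample was 0. Gene symbols and identifiers are those of the file; 16920 of the 17034 identifiers were found in the RefSeq GRCm38.p6 gene table (16814 protein-coding) and 114 were not. That table served for names and for the overlap of Nr1d1 with Thra. Transcript GC content and length were those of the longest GENCODE transcript of each gene. No coordinates are printed, because the build of the counts is not stated. Library totals were 12979945, 13412331 and 14266742 counts in WT and 14488500, 12390527 and 14390182 counts in TRa_mKO.

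Genes were kept by filterByExpr with a minimum count of 10, normalized by TMM and tested with the two-sided quasi-likelihood test of edgeR 4.0.16 (robust, genotype as the single factor) in R 4.3.3. Benjamini-Hochberg adjusted p below 0.05 counted as changed. The common biological coefficient of variation was 11.8%. Log2 fold changes are TRa_mKO over WT with their standard errors, and CPM are given as mean ± SD over 3 libraries per genotype. Intervals are 95% confidence intervals of the log2 fold change. Tested on simulated counts for the 13118 genes of this comparison, with 200 changed genes in each of 5 runs, the step recovered 53.6% of genes changed 1.5-fold, 84.8% at 2-fold, 98% at 3-fold and 98.4% at 4-fold, and 7.3% of its calls were false.

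The groups, the test, the gene lists, the rule for named genes and the first alternatives were fixed before the data were examined. The rule names Thra, Thrb, Pink1, the 12 genes with the largest increase and the 12 with the largest decrease among those that passed, had a mean log2 CPM of at least 1 and had all libraries of the genotypes apart (clone-like symbols skipped), and up to 4 members of each list with the smallest p. Some genes that the rule names are not reported here. Members that a list's description calls for, such as Myh7 and Myh4, are given as values. There were 36 lists, 35 of them with enough tested members (at least 3), on thyroid hormone action, mitophagy and mitochondria, muscle fibre type and development, metabolism, stress responses and other cell types. Lists were tested with limma 3.58.1, by camera with a preset correlation of 0.01 and again with an estimated one, and by fry, adjusted over the lists. Camera called 7 lists (5 upward, 2 downward), camera with an estimated correlation 0, and fry 2. A list passes fry when its genes move, on balance, one way, which sets it against no other genes; it passed for developmental genes (adjusted p = 0.0116) and neuromuscular junction genes (adjusted p = 0.00271).

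Alternatives were DESeq2 size factors in edgeR, library size only, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the 10 most abundant genes left out, the replicate number as a block, each library left out in turn, other thresholds and a minimum fold. After the data were seen, 3 were added: the library highest in haemoglobin of each genotype left out together, genes with shared reads left out, and a loess correction for GC content and transcript length (12988 genes, 99% of those tested). Scripts ran in R and Python 3.11.15.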

Results

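Polyadenylated RNA was sequenced from the gastrocnemius, a mixed hindlimb muscle, of 8-week-old male mice. Mice labelled TRa_mKO carried floxed copies of Thra, the gene of thyroid hormone receptor alpha, together with Cre recombinase expressed from Myf5, a gene of early myogenic cells. Their WT littermates carried the floxed copies without Cre. The series design counts n = 3 mice per genotype, and each genotype is represented by 3 libraries. Total counts lay between 12390527 and 14488500 per library, a ratio of 1.17. Counts above 0 were seen for 15467 to 15707 of the 17034 genes with values. The 10 most abundant genes took 16.2% to 19.5% of the counts of a library. No pair of libraries agreed within sampling noise, as the chi-square per degree of freedom was 7.78 to 18.85 within a genotype and 27.35 to 40.36 between genotypes. The first principal component parted the genotypes and held 43.2% of the variance. Haemoglobin transcripts summed to 1793 CPM (normalised read counts scaled to the library size) in WT replicate 1 and 1606 CPM in TRa_mKO replicate 3, against 481 to 907 CPM in the other libraries.

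The single comparison of the design asks which transcripts differ between muscle labelled TRa_mKO and WT muscle, in a series concerned with muscle loss, mitophagy and the placement of Pink1 mRNA at mitochondria. The targeted gene came first. Thra (gene ID 21833) measured 78.8, 92.8 and 96.9 CPM in the WT libraries and 129, 118 and 101 CPM in the libraries labelled TRa_mKO (89.5 ± 9.46 and 116 ± 14, mean ± SD, n = 3 each). The log2 fold change of 0.37 (SE 0.12, 95% confidence interval 0.11 to 0.63) did not pass the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.117). Thra counts were thus not lower in the libraries labelled TRa_mKO, and every direction given here rests on the labels. A gene-level count adds the reads of all exons, and the exons that the floxed allele loses are not given in the sources used here, so this count checks neither the deletion nor the labels. Thra also overlaps Nr1d1, a repressor of the circadian clock (327 CPM in WT and 357 CPM in TRa_mKO, adjusted p = 0.775), and shares reads with other features. Thrb (gene ID 21834), which encodes the other thyroid hormone receptor, fell in the libraries labelled TRa_mKO, from 28 ± 2.7 to 14.7 ± 0.659 CPM (log2 fold change -0.93, SE 0.10, adjusted p = 0.00125), and it too shares reads.

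**Figure D1:**
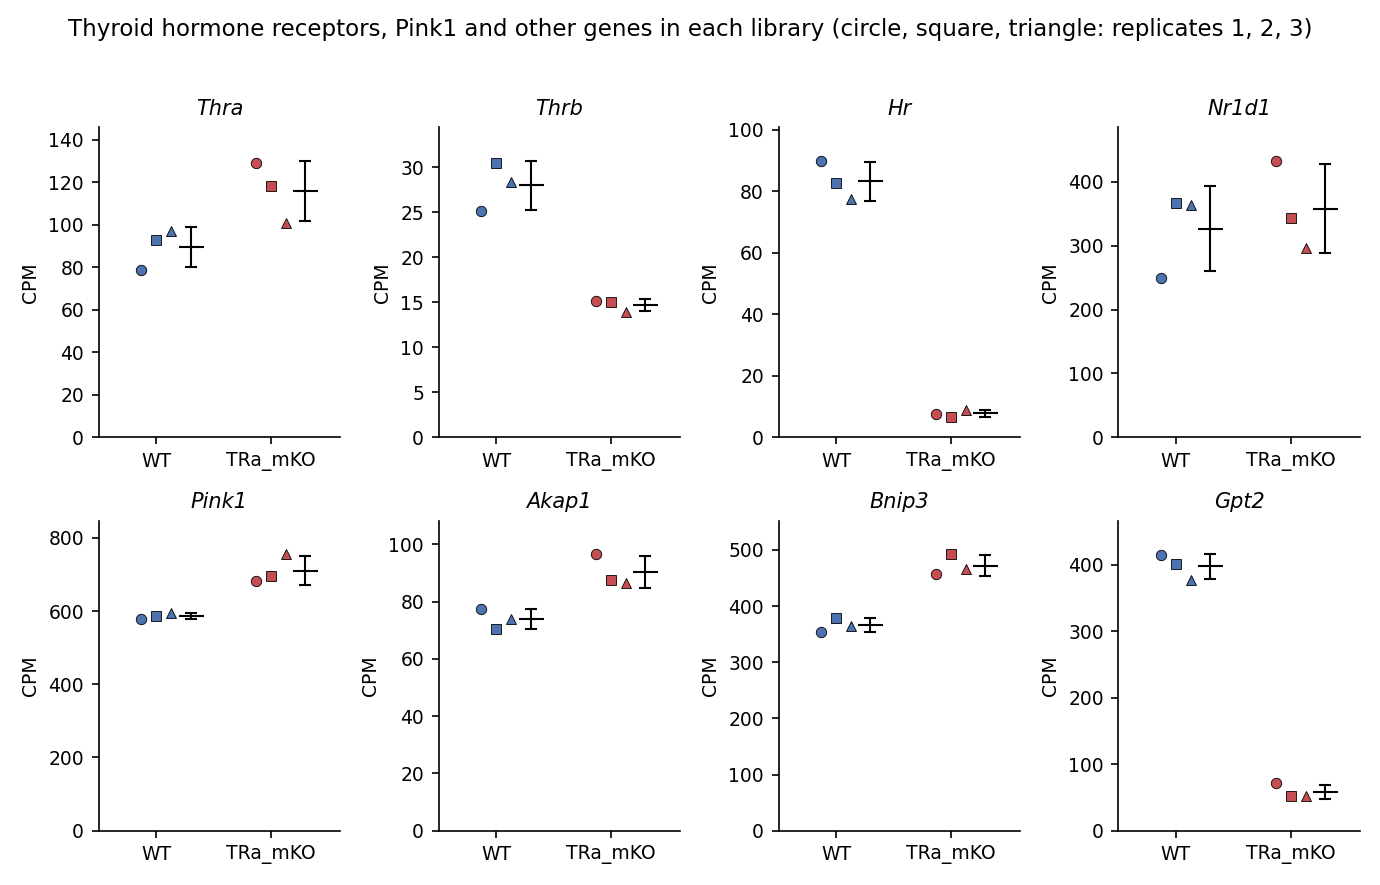
Normalised read counts (CPM) of 8 genes in each library of WT and TRa_mKO gastrocnemius, with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD (n = 3). Hr and Gpt2 sit lower in every library labelled TRa_mKO (7.79 and 58.5 CPM on average) than in any WT library (83.4 and 398 CPM), whereas Thra does not.

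In the libraries labelled TRa_mKO, genes of developing muscle (9 of 21 tested), denervation and the neuromuscular junction (8 of 23, with 1 lower), slow fibres (6 of 17, with 1 lower) and fatty acid oxidation (9 of 30) rose. Of the glycolysis and glycogen list, 7 of 30 genes fell, mostly genes of glycogen metabolism. Thyroid hormone responsive genes went both ways (3 higher and 3 lower of 25) and were called as a list by camera, downward, only where genes with shared reads were left out (adjusted p = 0.0326). The 5 other lists were called by limma camera with a preset correlation, and 0 lists with an estimated one. Myh3, the embryonic myosin heavy chain (gene ID 17883), rose 12-fold from 2.25 ± 0.486 to 27.3 ± 3.89 CPM (n = 3, SE of the log2 fold change 0.18, adjusted p = 9.01e-06). Hr, a nuclear receptor corepressor and a classical thyroid hormone target (gene ID 15460), was 10.6-fold higher in WT, at 83.4 ± 6.36 against 7.79 ± 1.15 CPM (SE 0.12, adjusted p = 7.88e-07). Gpt2, the mitochondrial alanine aminotransferase (gene ID 108682), was 6.80-fold higher in WT, at 398 ± 18.9 against 58.5 ± 10.9 CPM (SE 0.14, adjusted p = 9.01e-06). Of 13118 genes tested, 547 changed (331 higher, 216 lower, 4.17%), and 162 of these changed at least 2-fold. Of the 547, 58 share reads with other features. With library sizes alone, without a composition factor, 213 genes were higher and 255 lower, so that 45.5% in place of 60.5% of the calls were upward. The count was 360 without WT replicate 2 (178 higher), 309 without WT replicate 3 (186 higher, 123 lower), 209 without TRa_mKO replicate 2 (135 higher, 74 lower), and 139 genes were lower without TRa_mKO replicate 3. Leaving out the haemoglobin-rich library of each genotype, a choice made after seeing the data, gave 267 genes (177 higher, 90 lower).

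**Figure D2:**
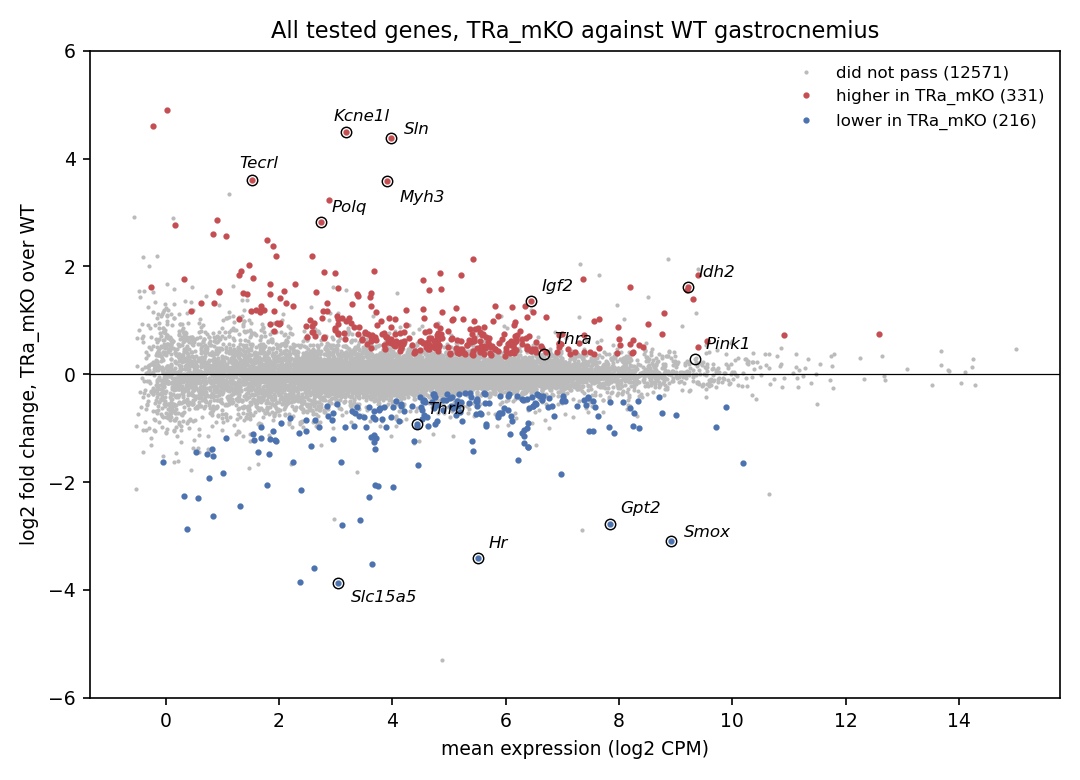
Log2 fold change of TRa_mKO over WT (vertical axis) against mean log2 CPM (horizontal axis) for each of the 13118 tested genes, one point per gene. Red points mark the 331 genes higher and blue points the 216 genes lower in the libraries labelled TRa_mKO, and grey points did not pass the test.

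Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest increases went to Kcne1l, a potassium channel accessory subunit (22.7-fold, from 0.744 ± 0.183 to 17.1 ± 9.73 CPM, adjusted p = 0.0104), and Sln. The latter encodes sarcolipin, a small inhibitor of the sarcoplasmic reticulum calcium pump (20.8-fold, from 1.44 ± 0.446 to 29.9 ± 12.9 CPM, adjusted p = 0.00624). Tecrl rose 12.1-fold (adjusted p = 0.0125), and Myh8, the perinatal myosin heavy chain, 9.44-fold (adjusted p = 0.000346, shared reads). Polq, a DNA polymerase, rose 7.06-fold (adjusted p = 0.000284), and the neurotrophin gene Bdnf 5.92-fold (adjusted p = 0.00979). Cspg4b, Col26a1, Dlk1, Atp1b4 and Fndc3c1 rose 5.17-fold, 4.60-fold, 4.56-fold, 4.39-fold and 4.08-fold, with adjusted p of 0.00111, 0.000655, 0.0115, 0.0118 and 0.0056. Among the decreases, the transporter gene Slc15a5 was 14.6-fold higher in WT (adjusted p = 0.0241). Neto2, an auxiliary subunit of kainate receptors, Prune2 and Fgfbp1 were 12.1-fold, 11.4-fold and 6.95-fold higher in WT (adjusted p = 9e-05, 2.46e-05 and 6.54e-05). Smox, spermine oxidase, was 8.59-fold higher in WT (869 ± 207 against 101 ± 63.8 CPM, adjusted p = 0.0285, shared reads). Dusp14, Slc30a2, Sctr and Ces1d were 6.52-fold, 4.81-fold, 4.40-fold and 4.26-fold higher in WT (adjusted p = 0.000446, 0.0125, 0.00125 and 0.000446). Calls ended for Kcne1l without WT replicate 1, 2 or 3 (adjusted p = 0.0511, 0.0562 and 0.0578) and with limma-voom (0.0862) and for Tecrl without WT replicate 2 or 3 (0.0513 and 0.06). They also ended for Atp1b4 without WT replicate 1 or TRa_mKO replicate 3 (0.0553 and 0.0679), for Bdnf without WT replicate 3 (0.0528), for Dlk1 and Slc30a2 without TRa_mKO replicate 2 (0.0537 and 0.0595), and for Sln and Tecrl with limma-voom (0.0563 and 0.0691). Slc15a5 did not pass without WT replicates 1 or 2 or TRa_mKO replicates 2 or 3 (adjusted p = 0.0605 to 0.099), nor Smox when any library but TRa_mKO replicate 1 was left out (0.0619 to 0.1). Neither passed without a filter on low counts (0.0668 and 0.0769). Without the haemoglobin-rich libraries, calls ended for Sln, Tecrl, Dlk1, Atp1b4, Slc15a5, Smox and Slc30a2 (0.0546 to 0.251).

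Thyroid hormone target genes moved in both directions. Of 25 tested genes known to respond to thyroid hormone, 3 rose and 3 fell (6 and 4 when adjusted over the list alone). Besides Hr, the fallers were Klf9, a transcription factor gene (WT 1.43-fold higher, 316 ± 35.6 against 222 ± 5.04 CPM, adjusted p = 0.0283), and Thrsp, a lipogenic regulator (WT 1.52-fold higher, 27.1 ± 1.93 against 17.8 ± 2.21 CPM, adjusted p = 0.016). Cpt1b, Atp2a2 and Myh2 were the risers. The set test (limma camera) did not call the list (adjusted p = 0.558), and its direction was downward although the median log2 fold change was 0.18 and the mean 0.11. Camera looks for a shift in a single direction, so changes both ways can cancel in it. The list set no expected direction for its members. Fry without regard to direction, which sets a list against no other genes, passed the target list (adjusted p = 2.72e-06). It also passed mitophagy genes (adjusted p = 9.26e-05), of which edgeR called 1. Genes of mRNA targeting and import (0.0273) and autophagy and lysosome genes (0.0124) passed too, of which edgeR called 0 each. A pass is thus not particular to thyroid hormone targets. With genes that share reads left out, a choice made after seeing the data, camera called the target list downward (adjusted p = 0.0326, median 0.06). That step removed Myh7, Myh2, Strbp, Dbp and Myh1 (log2 fold change 1.96, 0.73, 0.51, 0.41 and 0.38) and Myh4 (-0.2). Among 15 genes of thyroid hormone receptors and transport, 1 rose and 1, Thrb, fell, with 3 higher and 1 lower when adjusted over the list alone and a median of 0.14 (set test adjusted p = 0.558). The target list counted 5 higher (2 lower) without WT replicate 1, and 1 higher without WT replicate 3 (1 lower), TRa_mKO replicate 1 (2 lower) or TRa_mKO replicate 3 (2 lower), and the receptor list 2 lower without TRa_mKO replicate 1. Single calls ended for Klf9 when any library but WT replicate 1 was left out (adjusted p = 0.0588 to 0.112) and for Thrsp without WT replicate 1 or 3 (0.051 and 0.0579). The receptor list counted 0 higher without WT replicates 1 or 3 or TRa_mKO replicates 2 or 3.

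Of 21 tested genes of developing and regenerating muscle, 9 rose and 0 fell (13 and 1 when adjusted over the list alone), with a median log2 fold change of 0.66. The camera test gave an adjusted p of 3.5e-22, and an adjusted p = 0.0616 with an estimated correlation. Besides Myh3 and Myh8, Igf2, a fetal growth factor, rose 2.54-fold (49.3 ± 2.14 to 125 ± 17.5 CPM, adjusted p = 0.000346), and Peg3, an imprinted zinc finger gene, 3.41-fold (74.6 ± 5.68 to 254 ± 62.3 CPM, adjusted p = 0.000763). For the fallers, 1 member had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Without the haemoglobin-rich library of each genotype, 4 members rose.

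Neuromuscular junction and denervation genes showed 8 members higher and 1 lower of 23 tested (10 and 1 when adjusted over the list alone), with a median of 0.28. The camera test gave an adjusted p of 1.44e-07, and an adjusted p = 0.0616 with an estimated correlation. The estimate was -0.018, below the preset 0.01, so correlation among the members does not account for the larger p. Subunits of the acetylcholine receptor rose: Chrna1 2.04-fold (24.9 ± 1.89 to 50.8 ± 3.3 CPM, adjusted p = 0.000446) and Chrnd 2.52-fold (4.02 ± 0.582 to 10.2 ± 0.738 CPM, adjusted p = 0.00162). Colq, which anchors acetylcholinesterase at the synapse, rose 1.88-fold (adjusted p = 0.00267), and the adhesion molecule gene Ncam1 1.52-fold (adjusted p = 0.00973). The member that fell was Sema6c (adjusted p = 0.0398). Markers of Schwann cells and nerve had a median of -0.58 (camera adjusted p = 0.0966, and 0.907 with an estimated correlation). With DESeq2 and the preset correlation, camera called them downward (adjusted p = 0.0054). Higher members of the junction list numbered 5 without WT replicate 3, 4 without TRa_mKO replicate 2 and 4 without the haemoglobin-rich library of each genotype, where Ncam1 no longer passed (adjusted p = 0.0851). With 1 library left out, Sema6c passed without WT replicate 1 and not without each other library (adjusted p = 0.0525 to 0.118).

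Of 17 slow-fibre genes tested, 6 rose and 1 fell (14 and 1 when adjusted over the list alone), with a median log2 fold change of 1.43. The camera test gave an adjusted p of 1.55e-15, and an adjusted p = 0.5 with an estimated correlation. Casq2, the calcium store protein of slow and cardiac fibres, rose 2.41-fold (47.5 ± 4.84 to 115 ± 13.2 CPM, adjusted p = 0.000446), Myoz2, a Z-disc protein gene, 2.03-fold (132 ± 32.1 to 269 ± 45.1 CPM, adjusted p = 0.0174), and Atp2a2, the slow calcium pump, 2.62-fold (350 ± 135 to 916 ± 162 CPM, adjusted p = 0.0292). Myl2 and Myl3, slow myosin light chains, rose 3.61-fold and 2.97-fold (adjusted p = 0.0376 and 0.0308). Myh7, the slow myosin heavy chain, measured 509, 137 and 183 CPM in WT and 965, 882 and 1390 CPM in the libraries labelled TRa_mKO and did not pass (adjusted p = 0.155, shared reads). The faller was Ankrd2, a stretch-responsive gene that WT held at 3.02-fold more (adjusted p = 0.0457). Members higher numbered 12 without WT replicate 1, 3 without WT replicate 2, 4 without TRa_mKO replicate 1, 2 without TRa_mKO replicate 2, 3 without TRa_mKO replicate 3 and 11 without the haemoglobin-rich libraries. With 1 library left out, Ankrd2 passed without WT replicate 3 and not without each other library (adjusted p = 0.0596 to 0.13). Single calls ended for Myoz2 without WT replicate 2 or TRa_mKO replicate 2 (adjusted p = 0.0579 to 0.0619), Atp2a2 without WT replicate 3 or any TRa_mKO replicate (0.0555 to 0.0965), Myl2 when any library but WT replicate 1 was left out (0.0555 to 0.11) and Myl3 without WT replicate 2 or any TRa_mKO replicate (0.0571 to 0.101).

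In the fast-fibre list, 1 of 21 members rose and 0 fell (1 and 0 when adjusted over the list alone), with a median of 0.09 and a camera adjusted p of 0.148. Myh2, the fast oxidative myosin heavy chain, rose 1.66-fold (1450 ± 330 to 2400 ± 13.7 CPM, adjusted p = 0.0352, shared reads). Myh4, the fast glycolytic heavy chain and an abundant muscle transcript, measured 21200 ± 5770 CPM in WT and 18500 ± 2460 CPM in the libraries labelled TRa_mKO (adjusted p = 0.675, shared reads). Calcium handling genes counted 6 higher and 0 lower of 29 tested (9 and 0 when adjusted over the list alone), with a median of 0.20. Besides Casq2, Sln and Atp2a2, the risers included the mitochondrial uniporter pore gene Mcu (1.45-fold, adjusted p = 0.0264) and Micu2 (adjusted p = 0.0443). No call was downward, and 1 member was lower at an unadjusted p under 0.05 (0 by DESeq2, 0 by limma-voom). The camera test of calcium handling gave an adjusted p of 2.24e-08, and an adjusted p = 0.628 with an estimated correlation. The fast-fibre list passed camera without WT replicate 2 (adjusted p = 0.00062) or TRa_mKO replicate 3 (0.0439) and with DESeq2 (0.0441), and with 1 library left out Myh2 passed without WT replicate 1 (2 members) and not without each other library (0.0615 to 0.137). Calcium handling counted 3 higher without WT replicate 3, TRa_mKO replicate 1 or TRa_mKO replicate 2, Mcu did not pass when any library but TRa_mKO replicate 3 was left out (0.0584 to 0.122), and Micu2 did not pass in any fit without 1 library (0.0569 to 0.154).

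Of 30 fatty acid oxidation genes tested, 9 rose and 0 fell (24 and 1 when adjusted over the list alone), with a median of 0.46. The camera test gave an adjusted p of 5.61e-16, and an adjusted p = 0.637 with an estimated correlation. Cpt1b, which commits fatty acids to mitochondrial import, rose 1.67-fold (321 ± 34.7 to 537 ± 24.8 CPM, adjusted p = 0.00581). Eci2 and Acads, enzymes of beta-oxidation, rose 1.49-fold and 1.53-fold (adjusted p = 0.00734 and 0.00754), and Slc25a20, the carnitine carrier, 1.52-fold (adjusted p = 0.0145). No call was downward, and 1 member was lower at an unadjusted p under 0.05 (0 by DESeq2, 0 by limma-voom). Nuclear-encoded oxidative phosphorylation subunits gave edgeR calls for 0 of 77 (0 when adjusted over the list alone), with a median of -0.03 and a camera adjusted p of 0.653. Of these, 2 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Of 30 genes of mitochondrial biogenesis and dynamics, Ppara, a receptor that drives lipid oxidation, rose 2.04-fold (10.8 ± 0.428 to 22.1 ± 2.54 CPM, adjusted p = 0.0013) and Esrrb 1.73-fold (adjusted p = 0.0189), with 3 higher when adjusted over the list alone, a median of 0, a mean of 0.09 and a camera adjusted p of 0.413. Fatty acid oxidation counted 19 higher without WT replicate 1, 4 without WT replicate 2 (1 lower), 3 without WT replicate 3, 4 without TRa_mKO replicate 2 and 5 without TRa_mKO replicate 3. Slc25a20 did not pass without WT replicate 2, WT replicate 3 or TRa_mKO replicate 2 (adjusted p = 0.056 to 0.0709), and Eci2 not without the haemoglobin-rich libraries (0.0587). The respiratory list passed camera downward without WT replicate 3 (median -0.17, adjusted p = 3.13e-06). That fit used the preset correlation, whereas the correlation estimated over all libraries was 0.85, so this p is too small. Biogenesis counted 5 higher without WT replicate 1, and Esrrb did not pass without WT replicate 2 or 3 or TRa_mKO replicate 2 or 3 (0.0569 to 0.0759), each of which left 1 gene of that list.

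Of 30 glycolysis and glycogen genes tested, 0 rose and 7 fell (0 and 9 when adjusted over the list alone), with a median of -0.20. The camera test gave an adjusted p of 3.12e-09, and an adjusted p = 0.637 with an estimated correlation. Gbe1, the glycogen branching enzyme, was 2.16-fold higher in WT (91.7 ± 13.4 against 42.5 ± 2.66 CPM, adjusted p = 0.000763), and Ugp2, which makes UDP-glucose, 1.95-fold (1110 ± 32.7 against 568 ± 57.6 CPM, adjusted p = 0.00163). Gys1, glycogen synthase, was 1.55-fold higher in WT (adjusted p = 0.0107, shared reads), and Fbp2, muscle fructose bisphosphatase, 1.89-fold (adjusted p = 0.0138). The other fallers were Pfkfb1, Phka1 and Phkb. No enzyme of the glycolytic sequence in the list, such as Pfkm, Aldoa, Gapdh, Pkm or Ldha, was called. No member was higher at an unadjusted p under 0.05 (0 by edgeR, 0 by DESeq2, 0 by limma-voom). Members lower numbered 4 without WT replicate 2, TRa_mKO replicate 2 or TRa_mKO replicate 3, and 3 without the haemoglobin-rich libraries, and Gys1 did not pass without TRa_mKO replicate 2 (adjusted p = 0.0685) nor Fbp2 without TRa_mKO replicate 3 (0.0601).

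**Figure D3:**
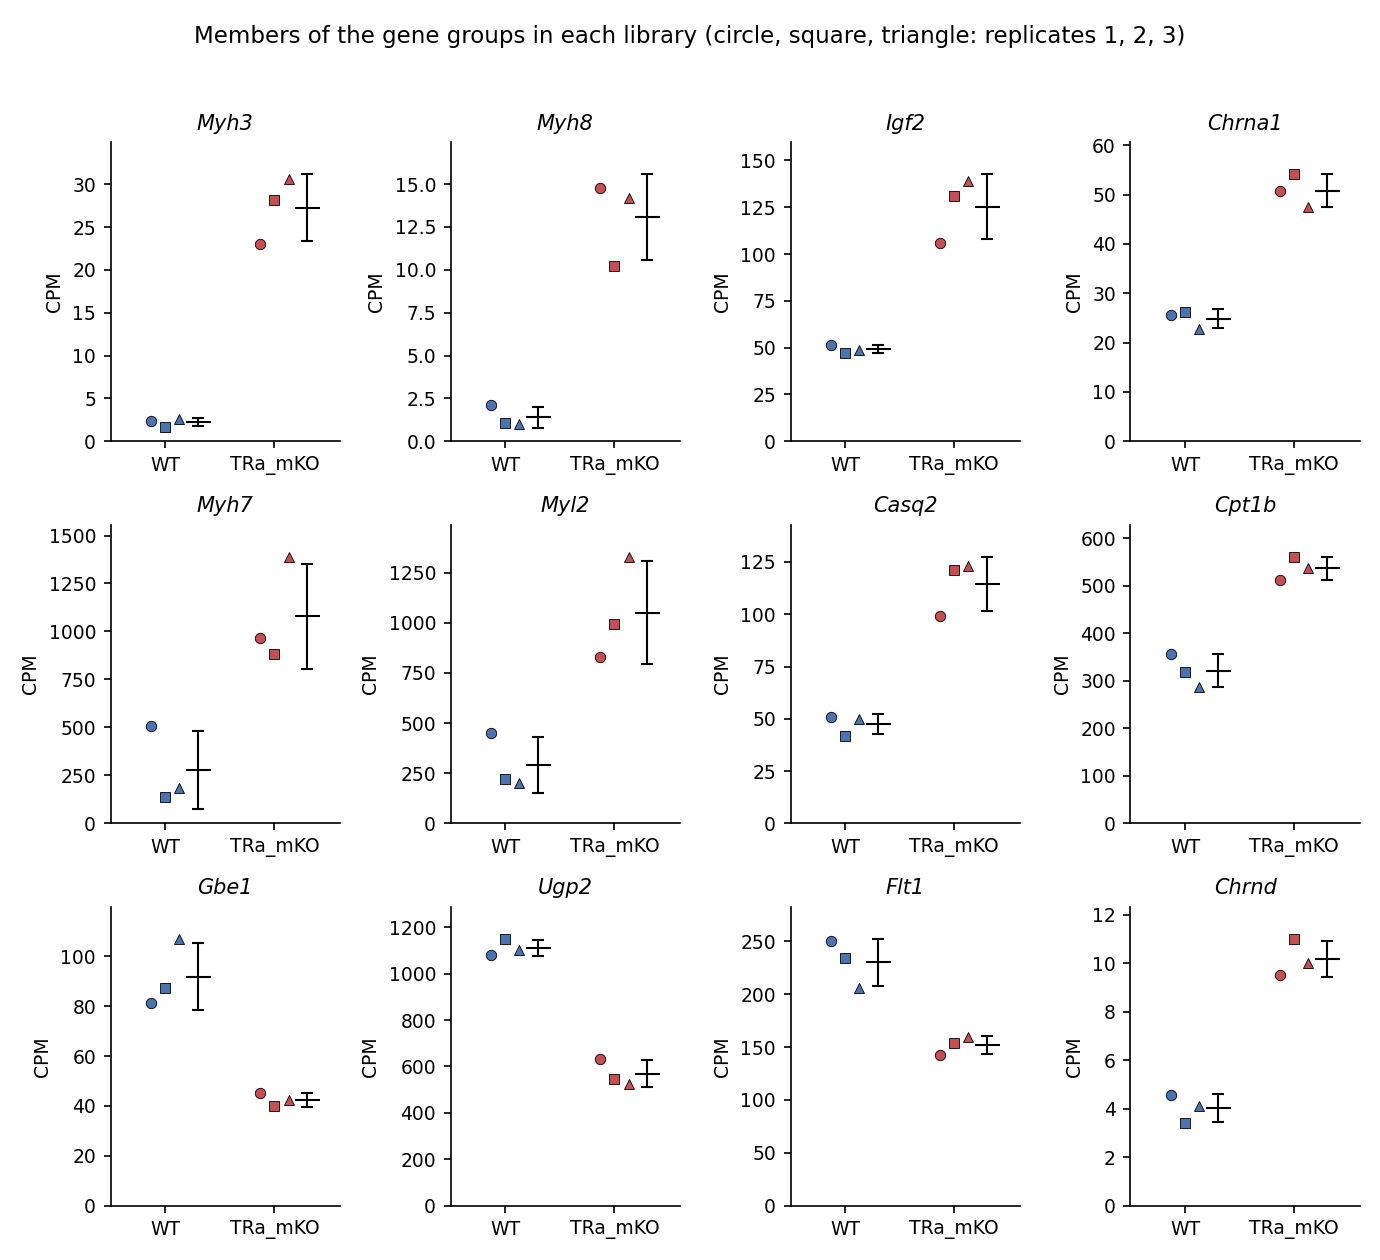
Normalised read counts (CPM) of 12 genes from the called lists in each library of WT and TRa_mKO gastrocnemius, with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD (n = 3). WT replicate 1 is the highest WT library for Myh7 (509 CPM).

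Mitophagy transcripts changed in 1 of 34 tested members. Pink1, the kinase that marks damaged mitochondria (gene ID 68943), measured 587 ± 8.05 CPM in WT and 710 ± 39.8 CPM in the libraries labelled TRa_mKO (log2 fold change 0.28, SE 0.10, 95% confidence interval 0.05 to 0.50), which edgeR did not call (adjusted p = 0.179) and DESeq2 did (adjusted p = 0.0494). Bnip3, a mitophagy receptor gene, measured 366 ± 12.5 and 472 ± 18.5 CPM (adjusted p = 0.0635 by edgeR and 0.00315 by DESeq2). The list had 1 higher and 0 lower when adjusted over the list alone, with a median of 0.04 that became -0.01 with library sizes alone (camera adjusted p = 0.484), and at an unadjusted p under 0.05 there were 5 members higher and 2 lower (3 and 0 by DESeq2, 1 and 0 by limma-voom). Genes that target mRNA to mitochondria or import proteins there gave edgeR calls for 0 of 20 (0 when adjusted over the list alone), with 1 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. Their median was -0.02, their mean 0.02 and the set test upward (adjusted p = 0.928). Akap1, an mRNA anchor of the outer membrane, measured 74 ± 3.53 and 90.3 ± 5.61 CPM (adjusted p = 0.105). Autophagy and lysosome genes gave edgeR calls for 0 of 47 (0 when adjusted over the list alone, median -0.01, camera adjusted p = 0.928), 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Without WT replicate 3, TRa_mKO replicate 2 or the haemoglobin-rich libraries, 0 mitophagy genes were called. Whole-tissue counts measure how much mRNA is present, not where in the cell it lies.

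Atrophy genes did not move as a group, with 2 of 32 higher and 3 lower (2 and 3 when adjusted over the list alone), a median of 0.06 and a camera adjusted p of 0.586. Fst, follistatin, an inhibitor of myostatin, rose 1.99-fold (6.01 ± 0.465 to 12 ± 0.523 CPM, adjusted p = 0.00273). Tnfrsf12a, the receptor of the cytokine TWEAK, was 1.75-fold higher in WT (adjusted p = 0.0294), and Trim54, a sarcomeric ubiquitin ligase, 1.41-fold (adjusted p = 0.039). Fbxo32 and Trim63, muscle ubiquitin ligases, measured 207 ± 76.7 and 344 ± 102 CPM in WT and 202 ± 85.6 and 220 ± 61.8 CPM in the libraries labelled TRa_mKO (adjusted p = 0.979 and 0.272). In insulin-like growth factor and mTOR signalling, Igf2 rose and the kinase gene Sgk1 fell among 24 members (2 and 1 when adjusted over the list alone, median 0.02, camera adjusted p = 0.413). Txnrd1 and Srxn1, antioxidant enzymes, fell among 25 members (0 and 3 when adjusted over the list alone, median -0.12, camera adjusted p = 0.138). Egr3 rose among 18 immediate-early genes (1 and 1 when adjusted over the list alone, median -0.09, camera adjusted p = 0.582), and Nfil3 among 19 clock genes (2 and 0 when adjusted over the list alone, median 0.13, camera adjusted p = 0.413). Of these genes, Fst and Igf2 passed in every fit without 1 library. Calls ended when any library but TRa_mKO replicate 1 was left out for Tnfrsf12a (adjusted p = 0.0578 to 0.126), Srxn1 (0.0608 to 0.178) and Egr3 (0.0669 to 0.16), when any but WT replicate 1 was left out for Trim54 (0.0618 to 0.132), when any but TRa_mKO replicate 3 was left out for Sgk1 (0.0708 to 0.177), and when any library was left out for Nfil3 (0.0764 to 0.135). Txnrd1 did not pass without WT replicate 2 or 3 or TRa_mKO replicate 2 or 3 (0.0852 to 0.117). Atrophy genes then numbered 1 higher in every fit without 1 library, and 0 lower without WT replicate 2 or TRa_mKO replicates 2 or 3, otherwise 1. Without TRa_mKO replicate 1 the growth factor list had 3 higher, and without WT replicate 2 the immediate-early list had 2. The antioxidant list passed camera downward without WT replicate 3 (adjusted p = 0.0343) or TRa_mKO replicate 2 (0.0284) and with DESeq2 (0.0447).

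**Figure D4:**
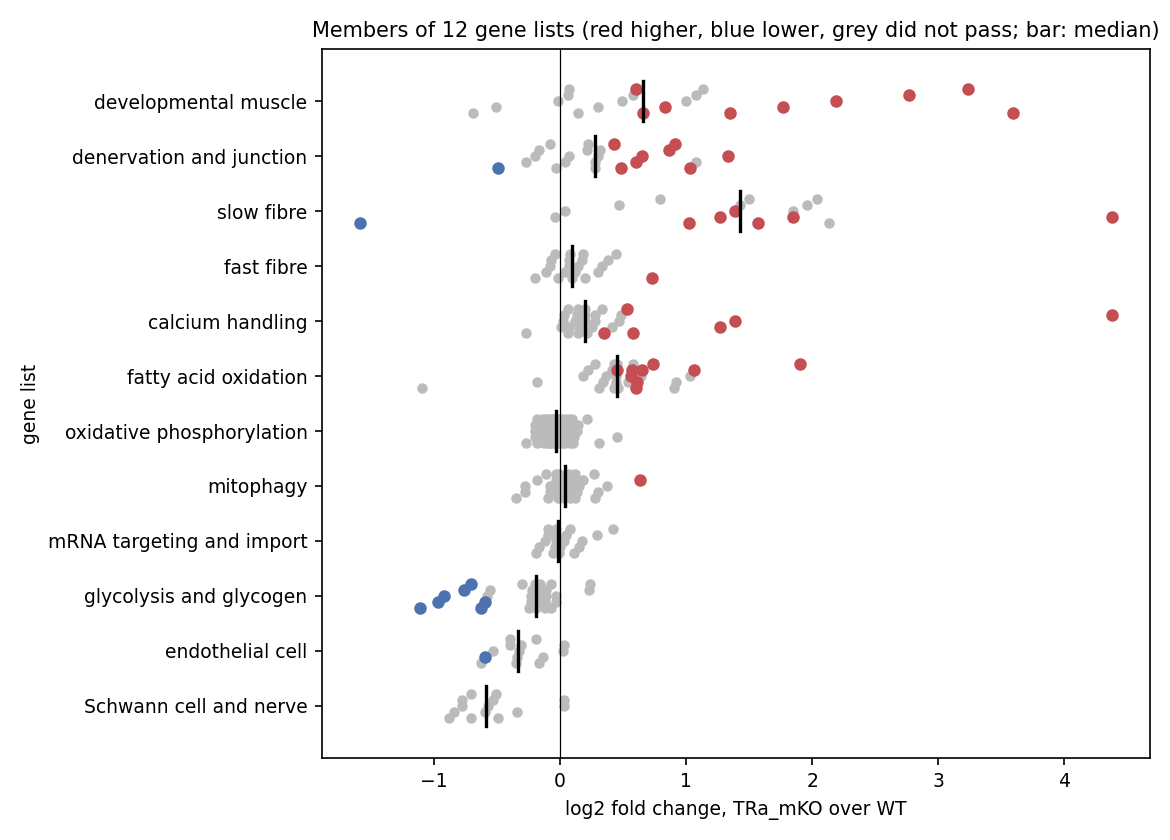
Log2 fold change of TRa_mKO over WT for each tested member of 12 gene lists, with one point per gene and a bar at the median of the list. Red and blue points passed the test as higher and lower, grey points did not, and medians reach 1.43 for slow-fibre genes and -0.58 for Schwann cell and nerve markers.

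Proteasome subunits (32 tested, median 0.02, camera adjusted p = 0.861), stress response and mitochondrial unfolded protein response genes (28 tested, -0.05, 0.558), heat shock genes (12 tested, -0.03, 0.558), interferon and inflammatory genes (18 tested, -0.21, 0.191) and genes flanking Thra and Myf5 (13 tested, 0.07, 0.704) had 0 members called by edgeR, over all genes and when adjusted over the list alone. Markers of other cell types were read in the same way. Endothelial markers had a median of -0.33, with Flt1, a receptor of vascular growth factor, 1.52-fold higher in WT (230 ± 22.4 against 152 ± 9.05 CPM, adjusted p = 0.0116) as the 1 call of 14 (0 higher and 2 lower when adjusted over the list alone). Their camera test gave an adjusted p of 0.000123, and an adjusted p = 0.907 with an estimated correlation. Of 12 smooth muscle and pericyte markers, Notch3 and Kcnj8 fell (adjusted p = 0.0399 and 0.0481; 2 and 2 when adjusted over the list alone, median -0.20, camera adjusted p = 0.413). Lists without a call over all genes were extracellular matrix and fibroblast (26 tested, median 0.11, camera adjusted p = 0.413), adipocyte (14, -0.10, 0.413), brown adipocyte (8, 0.18, 0.413, 1 higher when adjusted over the list alone), macrophage (14, -0.04, 0.404), lymphocyte and neutrophil (3, 0.07, 0.998), erythroid (8, 0.20, 0.558), Schwann cell and nerve (14, -0.58, 0.0966), tendon (12, -0.20, 0.395, 1 lower when adjusted over the list alone), and skin and hair (4, 0.15, 0.558). The 17 lists without a call held 347 genes, of which 27 had an unadjusted p under 0.05 (14 higher, 13 lower), DESeq2 called 2 higher and 5 lower, and limma-voom 0. Without WT replicate 2, 10 Schwann cell markers were called lower (median -0.93, camera adjusted p = 1.43e-29). Without WT replicate 1 camera called brown adipocyte (0.0255) and erythroid (0.000692) markers upward and tendon markers (0.0171) downward, as it did without the haemoglobin-rich libraries (0.0322, 0.00173 and 0.00239). Interferon genes passed downward without WT replicate 3 (0.0231) or TRa_mKO replicate 3 (0.0187), matrix genes upward without TRa_mKO replicate 1 (0.0193) and adipocyte markers downward without TRa_mKO replicate 2 (0.000791). In all of these fits camera used the preset correlation of 0.01. Over all libraries the estimated correlation was 0.862 for Schwann cell, 0.696 for erythroid and 0.735 for tendon markers. Where members move together like this, such p-values are too small. WT replicate 1 was also the WT library highest in haemoglobin. Flt1 did not pass without TRa_mKO replicate 2 (adjusted p = 0.0607), endothelial markers numbered 2 lower without WT replicate 3, 0 without TRa_mKO replicate 2 and 3 without TRa_mKO replicate 3. Notch3 lost its call when any library but TRa_mKO replicate 1 was left out (0.0768 to 0.168), and Kcnj8 when any but TRa_mKO replicate 3 was left out (0.0736 to 0.156).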

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

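The alternatives that leave out the haemoglobin-rich libraries or shared reads, or correct for GC content and length, were chosen after seeing the data. Against 547 genes changed (331 higher, 216 lower), edgeR with other size factors, no filter, a stricter filter, DESeq2, limma-voom, removal of the 10 most abundant genes, removal of shared reads and the GC correction gave counts within 1.5 times of these. Library size only gave 213 higher. A false discovery rate of 0.01 gave 173 (112 higher, 61 lower) and of 0.1 gave 934 (575 higher, 359 lower), and a 1.5-fold minimum gave 219 higher. Leaving out the haemoglobin-rich library of each genotype gave 267 (177 and 90), with fewer libraries in the fit. Leaving out 1 library gave 209 to 595 changed, 135 to 331 higher and 74 to 264 lower; 170 of the 547 genes passed in every such fit, and none changed sign in any alternative that tested it. With the replicate number as a block, 357 genes changed (216 higher, 141 lower), 321 of them among the 547. No sign of pairing by replicate number was seen. Deviations of same-numbered libraries correlated at -0.176, 0 and -0.006 across genes, and not every library correlated best with its own number. With so few libraries, a pairing by litter or day cannot be excluded. Against 7 lists, an estimated correlation called 0 and fry 2. Leaving out 1 library called 8 to 10, with the preset correlation alone. Thra lay between 0.28 and 0.46 on the log2 scale and passed in no alternative that tested it (adjusted p = 0.0685 to 0.326); leaving out genes with shared reads removed it. Of 2611 alternatives of 155 other named genes, 2391 kept direction and side of the threshold, 165 lost the call, 55 gained it and 0 changed sign; 29 of 63 called genes passed in every alternative that tested them. The cause of these differences was not tested. Mitochondrially encoded genes had no values, so leaving them out was not run. In simulated counts at this depth, 8.2% of genes changed 1.5-fold were recovered at a mean of 1 to under 10 CPM and 68.3% at 10 CPM or more, so that many changes of that size in rarer transcripts would be missed.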

Other observations

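Tests chosen only after the result was seen are the other splits, the exchange of single libraries, the correction for Nr1d1 reads and for GC content and length, both gene lists of the next 2 paragraphs, and the imprinted genes without members of earlier lists.

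Genes of branched-chain amino acid breakdown, a list chosen after values had been seen, had 10 of 24 tested members higher and 0 lower in the libraries labelled TRa_mKO (median log2 fold change 0.30, edgeR). Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase, rose 1.81-fold (32.4 ± 1.28 to 58.8 ± 6.49 CPM, n = 3, adjusted p = 0.00127, shared reads), Ivd, an isovaleryl-CoA dehydrogenase, 1.65-fold (126 ± 5.03 to 209 ± 16 CPM, adjusted p = 0.00292), and Bckdhb, a subunit of the dehydrogenase, 1.54-fold (29 ± 0.711 to 44.7 ± 2.24 CPM, adjusted p = 0.00269). The calls numbered 5 without WT replicate 1, 6 without WT replicate 2, 6 without WT replicate 3, 8 without TRa_mKO replicate 1, 5 without TRa_mKO replicate 2 and 7 without TRa_mKO replicate 3. Idh2, mitochondrial isocitrate dehydrogenase, rose 3.06-fold (294 ± 69.9 to 898 ± 179 CPM, adjusted p = 0.00292). Nnt, the mitochondrial transhydrogenase, measured 48.3, 38.9 and 36.2 CPM in WT and 90.8, 103 and 98.9 CPM in the libraries labelled TRa_mKO (2.37-fold, adjusted p = 0.000446).

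Polyamine genes, also chosen after values had been seen, had 1 of 16 tested members higher (Oaz2, ornithine decarboxylase antizyme, 1.45-fold, adjusted p = 0.0103, which did not pass without TRa_mKO replicate 2 at 0.0668) and 1 lower (Smox). Without TRa_mKO replicate 1 the list had 4 calls, and 1 without each other library. Amd1, which makes the aminopropyl donor of polyamine synthesis, measured 2430, 3030 and 2450 CPM in WT and 1100, 284 and 313 CPM in the libraries labelled TRa_mKO, and did not pass (log2 fold change -2.22, SE 0.60, adjusted p = 0.135). Amd1 and its near copy Amd2 both have counts that are not whole, with Amd2 at 5.84, 5.81 and 157 CPM in WT and 2.56, 0.726 and 0.969 CPM in TRa_mKO.

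With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05: the real split gave 547 genes, 1 split of the 10 gave as many, and the highest of the others gave 0.

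Thra counts were not lower in the libraries labelled TRa_mKO. All 6 of the 6 libraries correlated more closely with their own genotype (mean r 0.9861 to 0.9885 across genes) than with the other (0.9777 to 0.9794), which argues against single libraries exchanged between the genotypes. After the within-genotype slope on the overlapping gene Nr1d1 (0.167 CPM per CPM) was removed, Thra stayed 21.1 CPM higher in TRa_mKO (113 against 92, pooled SD 3.8), which argues against reads of Nr1d1 as the whole source. Hr, Klf9 and Thrsp, which thyroid hormone is known to raise, were 10.6-fold, 1.43-fold and 1.52-fold higher in WT, as the labels would have it. Of the same list 3 other genes rose, but the list set no direction for its members, so those rises do not weigh against the labels. The headers of the deposited count columns name the groups in the same way, as CRE for TRa_mKO and as WT. An exchange of whole groups made before the columns were named is not excluded by these values or headers and stays open. Reads from exons that the deleted allele may keep stay open too, as no exon-level counts were used here.

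Embryonic and perinatal myosins, Igf2 and Peg3 were higher together, and after the correction for GC content and gene length, 4 of the 4 genes Myh3, Myh8, Igf2 and Peg3 still passed, which argues against that bias as the whole cause. Denervated fibres would raise genes such as Chrng, Runx1, Ncam1, Myog and Gadd45a: Ncam1 passed (adjusted p = 0.0851 without the haemoglobin-rich libraries), Runx1, Gadd45a and Myog did not (log2 fold change -0.03, 0.07 and 1.08), and Chrng, with 31 counts in all, was not tested. Regenerating fibres or more progenitor cells would raise Pax7, Myod1, Myog, Mymk, Mymx and Cdh15: the tested 5 had a median of 0.66 (SD 1.3), and Mymx had 24 counts. Pax7 and Mymk passed upward while Myod1 lay at -0.69 (adjusted p = 0.0855) and Cdh15 at 0.06, and Pax7 lost its call when any library but WT replicate 2 was left out (adjusted p = 0.0527 to 0.0916) and Mymk when any but TRa_mKO replicate 1 was left out (0.0608 to 0.117). Neither explanation can be told apart from the genotype by these values, because the members spread too widely, and an effect of the genotype itself stays open too. Genotype here means floxed Thra with Cre expressed from Myf5 against floxed Thra without Cre. Loss of Thra therefore cannot be told apart from an effect of that Cre.

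Imprinted genes seen first among the risers were Igf2, Peg3, Plagl1, Zim1, Rtl1 and Ddc (2.54-fold, 3.41-fold, 3.02-fold, 2.06-fold, 2.25-fold and 7.33-fold). A candidate explanation, a shared rise of imprinted genes, was tested on 35 others from a list of 66 written before their values were seen. Of these 4 rose, 0 fell, and the median was 0.08: Zdbf2 passed without each library, Dlk1 not without TRa_mKO replicate 2 (adjusted p = 0.0537), Ppp1r9a not without WT replicates 1 to 3 or TRa_mKO replicate 2 (0.0686 to 0.138), and Trappc9 not when any but TRa_mKO replicate 3 was left out (0.0701 to 0.162). Camera gave p = 0.0341 upward, p = 0.0722 with an estimated correlation, and fry p = 0.0106. The estimated correlation was 0.001, below the preset 0.01, so correlation among the members does not account for the larger camera p. Without Dlk1, Cdkn1c, Grb10 and Calcr, which also stood in earlier gene lists, the other 31 had a median of -0.01 (3 higher, 0 lower), camera p = 0.396 (p = 0.517 with an estimated correlation) and fry p = 0.197, so a shared rise beyond a few genes stays open.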
